A study of Mus musculus with 12 samples.

How the data were processed

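The samples were 12 arrays with 2 colours each. Per the labels, 6 arrays carried RNA of terminal end buds and 6 carried RNA of mature ducts in Cy5, and all carried RNA of epithelium-free distal stroma of the mammary gland in Cy3. The mice were 5 weeks old and no array had its dyes swapped per the labels. The groups were taken from the labels, and replicate numbers only name the arrays in the order of their records. Slide numbers in the titles ran from 190 to 203. The labels do not state whether arrays came from separate animals or whether the stroma was 1 pool.

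The authors deposited a table of normalized ratios, taken here as log2 of epithelium over stroma. The scanner, the background correction and the normalization are not given in the sources used here. The base was read from the values: their sizes exclude base 10, base 2 is the usual choice, and natural logarithms remain possible. The direction follows the dyes of the labels. Array medians lay between 0.01 and 0.023, so the deposited values were already centred close to 0, and they were used as deposited. Centring on these medians moves no value by more than that.

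The table held 17589 probes, of which 129 had 1 missing value, all on 3 arrays. A probe was tested where it had values on at least 4 of the 6 arrays of each group, which left out no probe. Gene names came from the platform annotation given with the values, in which 14136 probes had 1 gene symbol, 13 had several and 3440 were unnamed here. The symbols of 14029 probes were matched by gene number to a RefSeq gene table of assembly GRCm38.p6, which updated 0 symbols. No coordinates were used. A gene was read from 1 probe, the one with values on most arrays and then the first in the table, giving 12913 genes. Of 998 genes with several probes, probes were called in opposite directions for 9 genes in terminal end bud against duct, 29 in terminal end bud against stroma and 18 in duct against stroma.

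All tests across probes used limma 3.58.1 in R 4.3.3. One fit of 2 group means over the 12 arrays gave each group's mean ratio against 0, the comparison with stroma, and the difference of the groups. Moderated tests with lmFit and eBayes were two-sided, p-values were adjusted by Benjamini-Hochberg over all probes, and the threshold was an adjusted p of 0.05. Log2 differences are given with the standard error of that fit. Stroma was never a sample of its own, so it counts as 1 control sample and its spread is left out.

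Before the data were examined, 36 gene lists of cell types, pathways and cell functions were written, with 985 members, of which 856 were on the array. Some lists share members. Of the measured genes, 14 of 25 luminal, 13 of 23 hormone response and 16 of 45 transcription factor genes were also in another list. Of these lists 35 had at least 5 measured members and were tested with limma's camera at a preset correlation between genes of 0.01, with camera at an estimated correlation, and with fry. Camera compares a list with the other genes, while fry asks whether its genes move on balance in one direction. These tests used the 17460 probes with all values, and p-values were adjusted over the lists of a comparison. The counts of genes that rose or fell are given over all probes tested and adjusted over the list alone. Marker genes of adipocytes, brown adipocytes, fibroblasts, endothelium, blood cells, muscle, nerve and skin were among the lists, since dissected epithelium can carry them.

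The rule for naming genes was also fixed before the data were examined. For each comparison it took the 8 highest and the 8 lowest genes past the threshold with the same sign on every array against stroma, or with group medians that differed like the means between the structures. It added up to 4 members past the threshold with the largest change from each list that passed camera, and 8 genes given whatever they showed: Krt18, Krt14, Cdh1, Fabp4, Adipoq, Col1a1, Gata3 and Mki67. Not every gene that the rule took is printed below. Genes named outside this rule are said to have been chosen after their values were seen.

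The fit was tested on simulated data with the probes' own spreads, the 17589 probes and 200 changed probes. For terminal end bud against duct it recovered 53.7% of changes of 0.5, 98.5% of changes of 1 and 100% of changes of 2 on the log2 scale, with 6 false calls. For terminal end bud against stroma it recovered 77.6%, 97% and 100%, with 14 false calls. Small differences were thus missed often between the structures.

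The alternatives tried were centring, quantile normalization, a common spread of the arrays, other probe filters, another variance model, array weights, neighbouring slides as a block, early against late slides as a term, a minimum size, each group's 6 arrays alone, each array left out in turn, and the mean of a gene's probes. Added after seeing the data were fits without the least correlated array of each group, fits within early and within late slides, and the gene lists under quantile normalization, a common spread and those subsets of arrays. Comparisons of list means between groups used exact permutation tests over all assignments of the arrays, and tests within ducts used exact sign-flip tests, all two-sided.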

Results

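Gene expression was measured in 2 epithelial structures of the mouse mammary gland at 5 weeks of age. Terminal end buds, the bulbous tips that lead the growing ductal tree, were compared with distal stroma, the fat pad ahead of the tree that holds no epithelium, on 6 arrays. Mature ducts were compared with the same kind of stroma on another 6 arrays. The tissues were microdissected from mice that carry a green fluorescent reporter driven by the beta-actin promoter. Each array carried epithelial RNA in Cy5 and stromal RNA in Cy3, so every value is a ratio of epithelium to stroma for 1 of 17589 probes, and 14136 of the probes name a single gene. The values are treated as log2 ratios. Their base is not given in the sources used here, and natural logarithms cannot be excluded, which would change sizes and folds but no sign, rank or p-value of the comparisons by limma.

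Arrays of the same structure resembled each other more than arrays of different structures. Pearson correlations over all probes had a median of 0.810 among terminal end bud arrays, 0.721 among duct arrays and 0.593 between the groups. These correlations run across genes, which are not independent replicates. Terminal end bud arrays had the wider ratios, with an SD over probes of 0.594 ± 0.041 (SD, n = 6) against 0.431 ± 0.037 (SD, n = 6) in ducts (two-sided exact permutation p = 0.00216, the smallest that the 6 and 6 arrays allow). No label says that the arrays came from separate animals, so p-values measure only the spread between these arrays, which may be technical. The number of arrays limits the precision of every value below.

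Keratins were among the genes most above distal stroma in terminal end buds. Krt8, Krt19 and Krt18, keratins of simple and luminal epithelium, were higher by 6.16 (SE 0.11), 5.41 (SE 0.17) and 5.19 (SE 0.17) on the log2 scale. All 3 had the same sign on all 6 arrays. The tight junction gene Cldn3 was higher by 4.51 (SE 0.15), the adhesion gene Epcam by 4.43 (SE 0.22), and the secretory genes Wfdc18 and Csn3 by 5.27 (SE 0.27) and 4.38 (SE 0.25). Among the lowest ratios, Ucp1, the uncoupling protein of brown fat, stood at -3.54 (SE 0.26), Cpt1b, which brings fatty acids into mitochondria, at -3.22 (SE 0.16), and Gpd1 at -3.21 (SE 0.23).

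In all, 4086 probes were higher and 3588 lower in terminal end buds than in stroma among the 17589 tested with limma, of which 657 and 612 differed by at least 2-fold. Stroma was only ever the reference, so it counts as 1 control sample whose own spread is left out. Without a dye swap in the labels a dye bias of single probes stays in these ratios. The other lowest genes were Cox6c at -3.04 (SE 0.20), Pygl at -2.99 (SE 0.11), Fabp3 at -2.97 (SE 0.19), Tmed5 at -2.89 (SE 0.13) and Ppara, a regulator of fatty acid oxidation, at -2.81 (SE 0.18). The remaining highest value, 5.38 (SE 0.14), came from a single probe that the platform assigns to Tada1, an assignment that was not verified and is in doubt. Adjusted p-values of these 16 genes lay between 1.02e-13 for Krt8 and 6.24e-08 for Gpd1. Among the genes given whatever they showed, Gata3 was higher by 3.75 (SE 0.17), Cdh1 by 1.94 (SE 0.18), Krt14 by 1.502 (SE 0.15), Col1a1 by 1.47 (SE 0.21) and Mki67 by 0.99 (SE 0.20), while Fabp4 was at -2.13 (SE 0.19). Adipoq was at -0.46 (SE 0.11, adjusted p = 0.00436), at -0.31 without terminal end bud replicate 5, and at -0.22 on slides up to 193 alone (adjusted p = 0.205). Those slides, 2 arrays per group and chosen after seeing the data, also ended the calls of Mki67 (adjusted p = 0.0548) and of the immediate early list named further on (adjusted p = 0.184). Csn3 was at 2.30 with the mean of its probes.

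Of 25 measured luminal genes, 23 rose and 0 fell in terminal end buds against stroma, and 24 rose when adjusted over the list alone (camera adjusted p = 8.92e-15, and adjusted p = 0.029 with an estimated correlation). Of 27 genes of the epithelial junction list, 24 rose and 1 fell (adjusted over the list alone, also 24 and 1). Among them were Spint2 by 4.07 and Rab25 by 3.23, which are not junction components themselves. Of 23 basal and myoepithelial genes, 15 rose and 1 fell, led by Actg2 at 2.66, Acta2 at 2.60, Krt5 at 2.53 and Krt17 at 1.93 (16 and 1 adjusted over the list alone). Of 45 mammary transcription factors, 30 rose and 4 fell, with Foxa1 at 2.81, Sox10 at 2.55 and Elf5 at 2.18 (31 and 5 adjusted over the list alone). These 3 lists passed camera with adjusted p = 1.64e-10, 5.15e-06 and 4.16e-07, and each had adjusted p = 0.0513 with an estimated correlation. Of 20 genes of milk proteins and secretory differentiation, 13 rose and 1 fell (14 and 2 adjusted over the list alone, camera adjusted p = 0.00021, and adjusted p = 0.029 with an estimated correlation).

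Cell division genes were also higher in terminal end buds than in stroma. Of 44 mitosis genes, 39 rose and 1 fell, with Cdc20 at 2.51, Cdk1 at 2.50, Stmn1 at 2.47 and Cenpa at 2.19 (40 and 1 adjusted over the list alone, camera adjusted p = 9.42e-13). Of 36 genes of S phase and replication, 32 rose and 1 fell, with Mcm6 at 2.32, Mcm3 at 1.84 and Rrm2 at 1.81 (32 and 1 adjusted over the list alone, camera adjusted p = 2.06e-11). Both lists had adjusted p = 0.136 with an estimated correlation. Of 34 cytosolic ribosomal proteins, 24 rose and 2 fell, both ways of adjusting alike, with Rpl6 at 2.03 (camera adjusted p = 1.33e-06, and adjusted p = 0.16 with an estimated correlation). Of 24 ribosome biogenesis genes, 19 rose and 1 fell, with Pa2g4 at 1.37 and Npm1 at 1.23 (20 and 2 adjusted over the list alone, camera adjusted p = 1.86e-06, and adjusted p = 0.0513 with an estimated correlation).

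Signalling and matrix lists rose in terminal end buds in part. Of 39 Wnt pathway genes, 22 rose and 3 fell, and the ligands Wnt6 at 2.11, Wnt4 at 1.57, Wnt2 at 1.39 and Wnt7b at 1.35 led them (23 and 3 adjusted over the list alone, camera adjusted p = 0.000164). Of 13 Hedgehog pathway genes, 6 rose and 0 fell, both ways of adjusting alike, with Gas1 at 1.27 and Dhh at 1.11 (camera adjusted p = 0.0078). Both lists had adjusted p = 0.0513 with an estimated correlation. Of 28 genes of the basement membrane and its receptors, 17 rose and 4 fell, with Col7a1 at 2.57 and Lama1 at 1.67 (18 and 4 adjusted over the list alone, camera adjusted p = 0.000185, and adjusted p = 0.108 with an estimated correlation). Of 21 immediate early genes, 13 rose and 3 fell, both ways of adjusting alike, with Junb at 1.28 and Myc at 1.08 higher and Dusp1 at -1.22 lower (camera adjusted p = 0.0221, and adjusted p = 0.522 with an estimated correlation). Other signalling lists had members that rose but did not pass camera. In the Notch pathway 13 of 23 rose and 3 fell (camera adjusted p = 0.0502). In FGF, EGF, IGF and HGF signalling 15 of 34 rose and 6 fell (0.0502). In axon guidance 18 of 38 rose and 7 fell (0.127). In hormone response 7 of 23 rose and 4 fell (0.133), and in matrix proteases and inhibitors 10 of 32 rose and 8 fell (0.858).

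Genes of fat, vessels and respiration fell in terminal end buds against stroma. Of 19 adipocyte genes, 17 fell and 0 rose, both ways of adjusting alike, with Pnpla3 at -2.48 and Slc2a4 at -2.13 (camera adjusted p = 2.94e-10, and adjusted p = 0.029 with an estimated correlation). All 9 brown adipocyte genes fell, with Cox8b at -2.64 and Cox7a1 at -2.56, and Cox7a1 spread widely between arrays (SD 1.21, n = 6). Of 17 endothelial genes, 14 fell and 1 rose, both ways of adjusting alike, with Pecam1 at -1.70 and Kdr at -1.47. Of 35 oxidative phosphorylation genes, 29 fell and 2 rose, both ways of adjusting alike, with Cox5b at -2.41 and Sdhc at -2.22. Of 17 genes of fatty acid synthesis, 15 fell and 1 rose, both ways of adjusting alike, with Elovl6 at -2.50 and Acacb at -2.25. The camera adjusted p was 1.18e-07 for brown adipocytes and for endothelium, 1.86e-11 for oxidative phosphorylation and 1.77e-07 for fatty acid synthesis, and each had adjusted p = 0.0513 with an estimated correlation. Genes of fibroblasts and fibrillar matrix went both ways, with 14 of 30 higher and 8 lower (adjusted over the list alone, also 14 and 8, camera adjusted p = 0.544, and 0.0437 on slides up to 193 alone).

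Milk protein genes were among those most above distal stroma in ducts. The caseins Csn3, Csn1s1 and Csn1s2a were higher by 6.25 (SE 0.25), 5.71 (SE 0.22) and 4.85 (SE 0.29) on the log2 scale in these glands, with the same sign on all 6 arrays. Krt18 and Krt8 were higher by 4.98 (SE 0.17) and 4.96 (SE 0.11), Epcam by 4.48 (SE 0.22), the mucin Muc15 by 4.19 (SE 0.25), and the probe assigned to Tada1 by 5.13 (SE 0.14). The lowest genes were Cpt1b at -2.05 (SE 0.16), Ucp1 at -1.82 (SE 0.26), Ppara at -1.76 (SE 0.18) and Cox8b at -1.74 (SE 0.16).

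Ducts had 2814 probes higher and 2138 lower than stroma with limma among the 17589 tested, of which 318 and 106 differed by at least 2-fold. The limits of a single reference and of the dyes hold here too. The other lowest genes were Fabp3 at -1.72 (SE 0.19), Slc27a2 at -1.69 (SE 0.16), Cox7a1 at -1.68 (SE 0.34) and the bicarbonate transporter Slc4a4 at -1.67 (SE 0.16). Adjusted p-values of these 16 genes lay between 2e-12 for Krt8 and 0.002 for Cox7a1. Gata3 was higher by 3.37 (SE 0.17), Krt14 by 2.79 (SE 0.15) and Cdh1 by 1.69 (SE 0.18), and Fabp4 was at -0.82 (SE 0.19). Col1a1 was higher by 0.77 (SE 0.21, adjusted p = 0.013), by 0.60 without duct replicate 2 (adjusted p = 0.0527), and by 0.51 on slides from 196 on alone (adjusted p = 0.18). Csn3 was at 3.46 with the mean of its probes. Mki67 at 0.50 (SE 0.20, adjusted p = 0.0838) and Adipoq at -0.21 (SE 0.11, adjusted p = 0.189) did not pass. Mki67 passed under quantile normalization (0.57, adjusted p = 0.0353), a common median absolute deviation (0.58, adjusted p = 0.0462) and array weights (0.57, adjusted p = 0.042). Adipoq passed with the 6 duct arrays alone (adjusted p = 0.0248) and without terminal end bud replicate 5, which enters the shared spread (adjusted p = 0.0362).

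Of 25 luminal genes, 24 rose and 0 fell in ducts against stroma, both ways of adjusting alike, with Cd24a at 4.07 (camera adjusted p = 6.97e-23). Of 23 basal and myoepithelial genes, 17 rose and 1 fell, with the contractile genes Acta2 at 3.24 and Tagln at 2.72 and the keratin Krt5 at 2.51 (19 and 1 adjusted over the list alone, camera adjusted p = 9.77e-12). Of 20 genes of milk proteins and secretory differentiation, 13 rose and 0 fell, both ways of adjusting alike (camera adjusted p = 9.83e-11). Of 27 genes of the epithelial junction list, 22 rose and 0 fell (23 and 0 adjusted over the list alone, camera adjusted p = 7.4e-14). Among them were Spint2 at 3.54 and St14 at 3.02, which are not junction components themselves. Of 45 mammary transcription factors, 27 rose and 1 fell, with Elf5 at 2.73 and Foxa1 at 2.27 (27 and 2 adjusted over the list alone, camera adjusted p = 1.53e-09). Of 23 hormone response genes, 13 rose and 1 fell, with Cited1 at 2.62 and Wnt4 at 1.71 (14 and 1 adjusted over the list alone, camera adjusted p = 0.000183). These 6 lists held with an estimated correlation, with adjusted p between 0.000833 for milk proteins and 0.0308. Several of them share members, so they are not 6 independent results.

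The calls of 3 further higher lists in ducts also held with an estimated correlation. Of 28 genes of the basement membrane and its receptors, 20 rose and 2 fell, with Lama5 at 1.69 and Lamb3 at 1.45 (22 and 2 adjusted over the list alone, camera adjusted p = 1.42e-07). Of 39 Wnt pathway genes, 15 rose and 1 fell, and the secreted inhibitors Wif1 at 1.79 and Sfrp2 at 1.76 led (16 and 1 adjusted over the list alone, camera adjusted p = 0.000374). The basement membrane and Wnt lists had adjusted p = 0.0308 with an estimated correlation. Of 38 axon guidance genes, 14 rose and 2 fell, both ways of adjusting alike, with Reln at 1.25 and Plxnb2 at 1.09 (camera adjusted p = 0.00281, and adjusted p = 0.0283 with an estimated correlation).

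Further lists passed camera in ducts but not with an estimated correlation. Of 30 genes of fibroblasts and fibrillar matrix, 18 rose and 0 fell, with Postn at 1.501, Fn1 at 1.28, Col3a1 at 1.04 and Mmp2 at 1.02 (18 and 1 adjusted over the list alone, camera adjusted p = 1.01e-05, and adjusted p = 0.259 with an estimated correlation). Of 34 genes of FGF, EGF, IGF and HGF signalling, 16 rose and 2 fell, with the receptor Fgfr2 at 2.36 higher and the ligand Fgf10 at -1.004 lower (17 and 2 adjusted over the list alone, camera adjusted p = 0.000553, and adjusted p = 0.0554 with an estimated correlation). Of 23 Notch pathway genes, 10 rose and 0 fell, with the target Hey1 at 1.32 and the ligand Dll1 at 0.86 (10 and 1 adjusted over the list alone, camera adjusted p = 0.0102, adjusted p = 0.134 with an estimated correlation, and 0.181 on slides up to 193 alone). Of 32 matrix proteases and inhibitors, 11 rose and 2 fell, with Adam10 at 1.17 and Mmp3 at 1.13 (12 and 2 adjusted over the list alone, camera adjusted p = 0.00731, and adjusted p = 0.13 with an estimated correlation). Of 34 cytosolic ribosomal proteins, 24 rose and 0 fell, with Rps6 at 1.76 and Rpl4 at 1.61 (25 and 3 adjusted over the list alone, camera adjusted p = 1.51e-10, and adjusted p = 0.073 with an estimated correlation). Of 24 ribosome biogenesis genes, 11 rose and 0 fell, with Npm1 at 1.04 (12 and 0 adjusted over the list alone, camera adjusted p = 0.000476, and adjusted p = 0.11 with an estimated correlation).

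Cell division genes lay closer to stroma in ducts, though unevenly between arrays. The mean of the mitosis list kept 60.3% of its terminal end bud log2 ratio in duct replicate 5 and 39.5% in duct replicate 2. On the other duct arrays it kept -2.16% to 16.6%. Of 44 mitosis genes, 7 rose and 1 fell, with Stmn1 at 1.04 and Cks1b at 0.53 higher and Ccnb2 at -0.68 lower (4 and 1 adjusted over the list alone, camera adjusted p = 0.0158, adjusted p = 0.592 with an estimated correlation, fry adjusted p = 0.107, and camera adjusted p = 0.0678 on slides from 196 on alone). Of 36 replication genes, 15 rose and 2 fell, with Mcm6 at 0.90 higher and Uhrf1 at -1.13 and Gmnn at -0.60 lower (17 and 2 adjusted over the list alone, camera adjusted p = 0.00281, and adjusted p = 0.456 with an estimated correlation).

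Fat and respiration genes fell in ducts as well. Of 19 adipocyte genes, 11 fell and 0 rose, both ways of adjusting alike, with Pnpla3 at -1.33, Gpd1 at -1.18 and Pparg, the master regulator of fat cells, at -1.02 (camera adjusted p = 9.96e-08, and adjusted p = 0.0308 with an estimated correlation). Of 9 brown adipocyte genes, 8 fell and 0 rose, and all 9 fell when adjusted over the list alone (camera adjusted p = 1e-08, and adjusted p = 0.0335 with an estimated correlation). Of 35 oxidative phosphorylation genes, 26 fell and 1 rose, with Cox6c at -1.55 and Sdhb at -1.47 (27 and 1 adjusted over the list alone, camera adjusted p = 1.45e-14, and adjusted p = 0.0308 with an estimated correlation). Of 17 endothelial genes, 9 fell and 0 rose, both ways of adjusting alike, with Kdr at -0.62 (camera adjusted p = 0.00259, and adjusted p = 0.204 with an estimated correlation). Of 17 genes of fatty acid synthesis, 9 fell and 2 rose, with Acacb at -0.79 and Thrsp at -0.79 lower and Fads2 at 0.62 higher (10 and 2 adjusted over the list alone, camera adjusted p = 0.000374, and adjusted p = 0.145 with an estimated correlation). Of 17 genes of cholesterol synthesis, 6 fell and 1 rose, with Fdft1 at -0.51 (-0.34 on slides from 196 on alone, adjusted p = 0.167) and Nsdhl at -0.47 (7 and 1 adjusted over the list alone, camera adjusted p = 0.00677, and adjusted p = 0.209 with an estimated correlation).

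**Figure D1:**
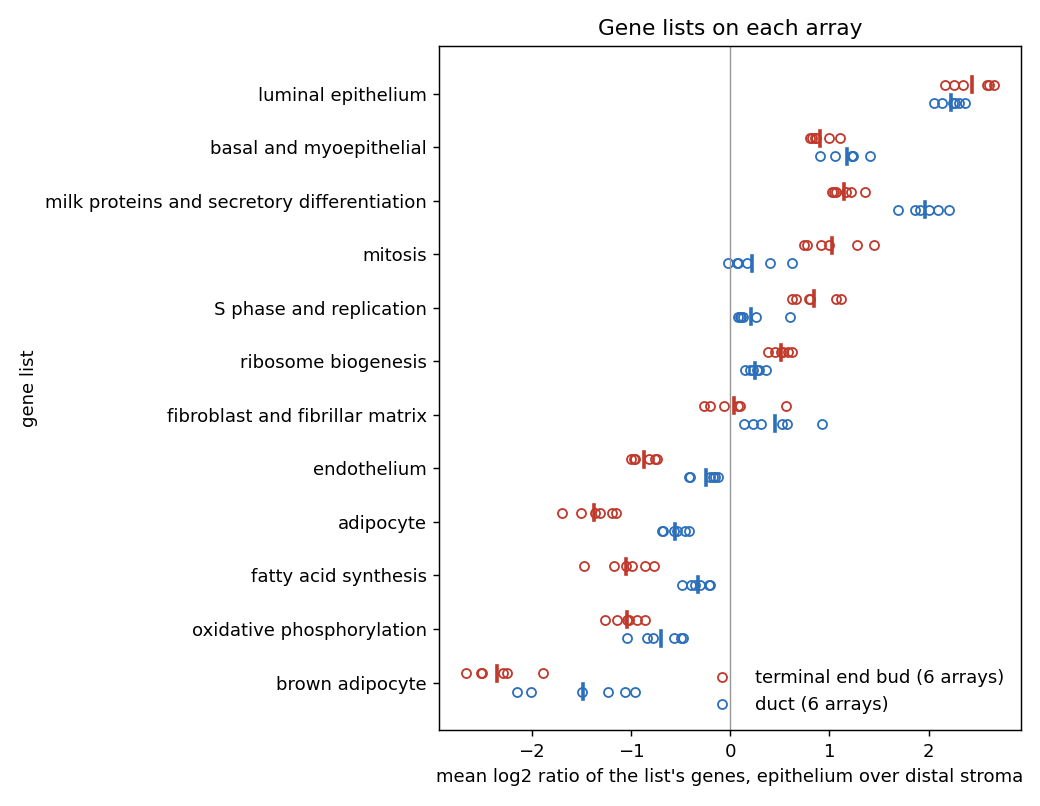
Mean log2 ratio of epithelium over distal stroma (horizontal axis) for the measured genes of 12 gene lists (vertical axis) on each array. Red circles are the 6 terminal end bud arrays, blue circles the 6 duct arrays, and vertical bars the group means, as at 1.03 and 0.22 for mitosis genes.

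Both structures shared many differences from stroma. Past the threshold in both, 1902 probes were higher and 1657 lower, where independent lists of these sizes would share 653.7 and 436.1. Unchanged groups simulated against 1 shared stroma sample that varied like an array shared 1855.2 and 1882 on average over 20 simulations, so these counts do not separate shared epithelial differences from the shared stroma. Each comparison with stroma held at least that many calls in the simulation. The counts of each structure against stroma given above may therefore in large part reflect a single stroma sample too. At 2-fold or more in both, 231 probes were higher and 101 lower, against 11.9 and 3.69 for independent lists and 38.6 and 41.4 in the simulation, so only these counts exceeded it clearly. Krt8, Krt18, Epcam, Csn3 and the probe assigned to Tada1 were among the 8 highest genes in both comparisons, and Ucp1, Cpt1b, Fabp3 and Ppara among the 8 lowest.

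The direct comparison of terminal end buds with ducts cancels any constant dye bias, and the stroma reference as far as it was alike on all arrays, which the labels do not state. Ducts held the higher level of milk and secretory genes. As the value in terminal end buds less that in ducts, Csn1s2a stood at -3.96 (SE 0.41) on the log2 scale and Csn1s1 at -2.78 (SE 0.31). Apod, a lipid-binding apolipoprotein, stood at -3.60 (SE 0.26) and Myh11, the myosin heavy chain of smooth muscle, at -2.16 (SE 0.17). Terminal end buds held the higher level of the cornified envelope genes Sprr1a at 2.88 (SE 0.26) and Sprr2a1 at 2.29 (SE 0.45), of the protease inhibitor Timp1 at 2.26 (SE 0.25), and of the mitotic genes Cdc20 at 2.13 (SE 0.20), Cenpa at 1.99 (SE 0.18) and Cdk1 at 1.76 (SE 0.29). Each value rests on 6 arrays per group.

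In all, 1463 probes were higher and 1832 lower in terminal end buds than in ducts among the 17589 tested with limma, of which 175 and 244 differed by at least 2-fold. The other genes at the extremes were Actg2, a smooth muscle actin, at 1.94 (SE 0.30) and the chaperone Hspa8 at 1.89 (SE 0.36) on the higher side. On the lower side they were Ttr, which carries thyroid hormone, at -2.28 (SE 0.26), the guidance factor Sema3c at -2.28 (SE 0.18), the matrix proteoglycan Ogn at -2.23 (SE 0.22) and Chil1 at -2.20 (SE 0.29). Adjusted p-values of these 16 genes lay between 1.83e-06 for Apod and 0.00241 for Sprr2a1. Of the genes given whatever they showed, Krt14 was lower in terminal end buds at -1.28 (SE 0.22, adjusted p = 0.000942) and Fabp4 at -1.31 (SE 0.26, adjusted p = 0.00307). Krt18 at 0.21 (SE 0.24), Cdh1 at 0.24 (SE 0.25), Adipoq at -0.24 (SE 0.16), Gata3 at 0.38 (SE 0.24) and Mki67 at 0.49 (SE 0.29) did not pass, with adjusted p = 0.6248, 0.573, 0.359, 0.325 and 0.288. Col1a1 at 0.70 (SE 0.29, adjusted p = 0.127) passed without terminal end bud replicate 3 (0.90, adjusted p = 0.0253) and without duct replicate 2 (0.87, adjusted p = 0.04997). It also passed with neighbouring slides as a replicate block (0.70, adjusted p = 0.0498).

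**Figure D2:**
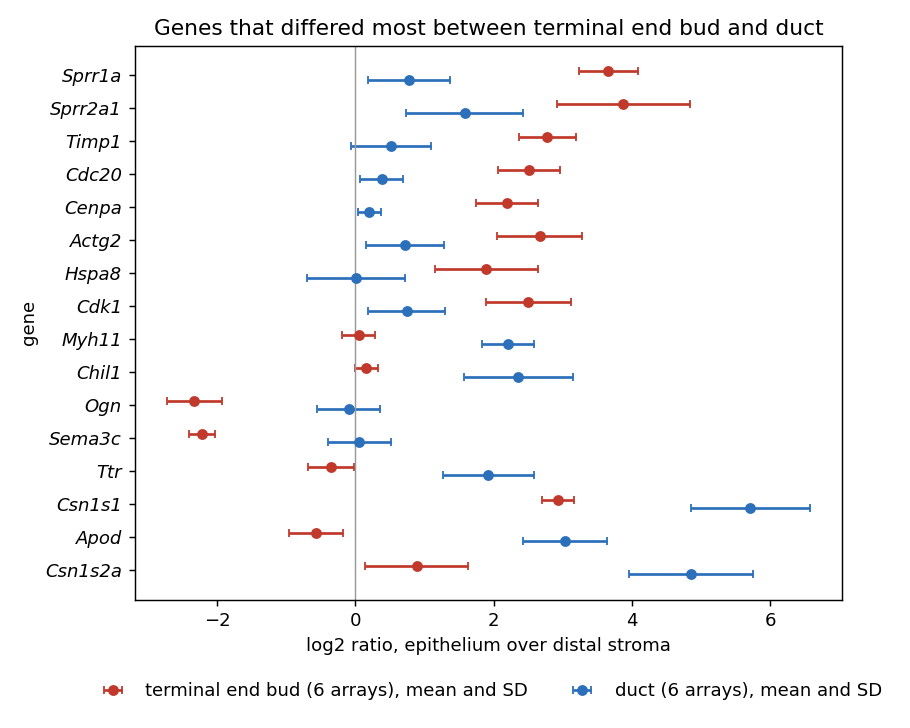
Log2 ratio of epithelium over distal stroma (horizontal axis) for the 8 genes most above and the 8 most below in terminal end buds against ducts (vertical axis). Points are means and bars SDs over 6 terminal end bud arrays (red) and 6 duct arrays (blue), as for Apod at -0.56 ± 0.39 and 3.03 ± 0.61.

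Cell division genes rose in terminal end buds against ducts. Of 44 mitosis genes, 26 rose and 0 fell, with Birc5 at 1.53 (SE 0.23) beside those above, and 33 rose when adjusted over the list alone (camera adjusted p = 3.67e-17, and adjusted p = 0.165 with an estimated correlation). Of 36 genes of S phase and replication, 25 rose and 1 fell, with the replication helicase genes Mcm6 at 1.42 (SE 0.28) and Mcm3 at 1.34 (SE 0.21) and the nucleotide enzymes Rrm2 at 1.41 (SE 0.13) and Dut at 1.27 (SE 0.12). Adjusted over the list alone, 27 rose and 1 fell (camera adjusted p = 4.89e-13, and adjusted p = 0.202 with an estimated correlation). Of 24 ribosome biogenesis genes, 12 rose and 1 fell, with Fbl at 0.77 (SE 0.10) and Nhp2 at 0.74 (SE 0.07) higher and Ncl at -0.74 (SE 0.07) lower (14 and 2 adjusted over the list alone, camera adjusted p = 7.79e-05, and adjusted p = 0.148 with an estimated correlation).

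Of 20 genes of milk proteins and secretory differentiation, 10 fell and 1 rose in terminal end buds against ducts, both ways of adjusting alike, with Lalba, which is needed for lactose synthesis, at -2.09 (SE 0.49) and Btn1a1, a protein of milk fat globules, at -1.96 (SE 0.13). This list alone among those tested held with an estimated correlation in this comparison (camera adjusted p = 0.000272, and adjusted p = 0.0465 with an estimated correlation). Of 17 genes of fatty acid synthesis, 10 fell and 1 rose, with Elovl6 at -2.01 (SE 0.13), Acacb at -1.46 (SE 0.20) and Me1 at -1.44 (SE 0.13) (12 and 2 adjusted over the list alone, camera adjusted p = 2.55e-06, and adjusted p = 0.148 with an estimated correlation).

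Markers of stromal cells moved with the groups too. Of 19 adipocyte genes, 12 fell and 0 rose in terminal end buds against ducts, with Gpd1 at -2.03 (SE 0.33), Retn at -1.57 (SE 0.31) and Cd36 at -1.23 (SE 0.17), and 14 fell and 1 rose when adjusted over the list alone (camera adjusted p = 1.75e-07, and adjusted p = 0.114 with an estimated correlation). Of 17 endothelial genes, 11 fell and 0 rose, with Pecam1 at -1.24 (SE 0.14), Emcn at -1.12 (SE 0.12) and Tie1 at -1.02 (SE 0.13) (12 and 1 adjusted over the list alone, camera adjusted p = 1.31e-07, and adjusted p = 0.119 with an estimated correlation). Of 30 genes of fibroblasts and fibrillar matrix, 11 fell and 4 rose, with Clec3b at -1.91 (SE 0.30) and Timp3 at -1.70 (SE 0.12) lower (13 and 5 adjusted over the list alone, camera adjusted p = 0.0243, and adjusted p = 0.611 with an estimated correlation). Fry gave an adjusted p of 0.0782 for this list. Of 6 mast cell genes, 2 fell and 0 rose, both ways of adjusting alike, and they were the protease genes Cpa3 at -1.36 (SE 0.18) and Tpsb2 at -0.70 (SE 0.15) (camera adjusted p = 0.0202, and adjusted p = 0.275 with an estimated correlation).

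Several lists passed only with the arrays' own spread, which was wider in terminal end buds. Of 9 brown adipocyte genes, 5 fell and 0 rose in terminal end buds against ducts, both ways of adjusting alike, with Ucp1 at -1.73 (SE 0.37) and Fabp3 at -1.24 (SE 0.27) (camera adjusted p = 0.00216, and adjusted p = 0.275 with an estimated correlation). Of 35 oxidative phosphorylation genes, 11 fell and 1 rose, with Cox6c at -1.48 (SE 0.28) and Cox6b1 at -1.23 (SE 0.17) (12 and 2 adjusted over the list alone, camera adjusted p = 0.00658, and adjusted p = 0.499 with an estimated correlation). Of 27 genes of the epithelial junction list, 7 rose and 1 fell, both ways of adjusting alike, with Lad1 at 1.21 (SE 0.30), Jup at 1.01 (SE 0.26) and Cldn3 at 1.003 (SE 0.21) (camera adjusted p = 0.0267, adjusted p = 0.541 with an estimated correlation, and fry adjusted p = 0.0954). Quantile normalization between arrays, added for the lists after seeing the data, ended these 3 calls with adjusted p of 0.862, 0.33 and 0.497, and turned the direction for oxidative phosphorylation. Among the genes named in this and the paragraph before, it also ended the calls of Gpd1 (-1.11), Cd36 (-0.58), Ucp1 (-0.72), Fabp3 (-0.40), Cox6c (-0.53) and Lad1 (0.88), and that of Fabp4 (-0.67). Division to a common median absolute deviation ended the same 3 list calls (adjusted p = 0.0976, 0.326 and 0.867) and those of Cldn3 (0.27), Lad1 (0.93), Ucp1 (-1.19), Fabp3 (-0.79), Cox6c (-1.06) and Fabp4 (-0.998).

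Of 13 Hedgehog pathway genes, 2 rose and 0 fell in terminal end buds against ducts, both ways of adjusting alike, and they were the ligand Dhh at 0.95 (SE 0.17) and Sufu, an inhibitor of the pathway, at 0.77 (SE 0.08) (camera adjusted p = 0.0166, and adjusted p = 0.119 with an estimated correlation). Of 21 immediate early genes, 3 rose and 3 fell, with Egr2 at 1.01 (SE 0.19) and Egr3 at 0.72 (SE 0.15) higher and Klf4 at -0.79 (SE 0.10) lower (9 and 3 adjusted over the list alone, camera adjusted p = 0.037, adjusted p = 0.593 with an estimated correlation, and fry adjusted p = 0.195). Of 20 genes of heat shock and unfolded protein, 5 fell and 2 rose, with Dnaja1 at -0.95 (SE 0.13) lower and Hspa8 higher (7 and 2 adjusted over the list alone, camera adjusted p = 0.0456, and adjusted p = 0.275 with an estimated correlation). Quantile normalization ended the calls of the Hedgehog and immediate early lists (adjusted p = 0.0833 and 0.118), and a common median absolute deviation that of the immediate early list (adjusted p = 0.0519). Averaging the probes of a gene ended the call of heat shock (adjusted p = 0.0606).

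Luminal and basal lists did not pass camera between terminal end buds and ducts over all arrays in the values as deposited. Of 25 luminal genes, 4 rose, 1 fell and 20 did not pass (adjusted over the list alone, also 4 and 1, camera adjusted p = 0.167, and 0.0346 on slides from 196 on alone). Of 23 basal and myoepithelial genes, 7 fell and 3 rose (8 and 6 adjusted over the list alone, camera adjusted p = 0.161, and fry adjusted p = 0.0104), and under quantile normalization the list was lower in terminal end buds (camera adjusted p = 0.00189). Of 23 hormone response genes, 5 fell and 1 rose (adjusted over the list alone, also 5 and 1, camera adjusted p = 0.107, fry adjusted p = 0.00161, and camera adjusted p = 0.013 under quantile normalization and 0.0287 on slides up to 193 alone).

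Subsets of the slides, chosen after seeing the data, ended further calls between terminal end buds and ducts. Slides up to 193 alone, 2 arrays per group, ended those of Hspa8 (1.03), Jup (0.93), Cldn3 (1.095), Birc5 (1.23), Egr2 (0.71) and Egr3 (0.48) among the higher genes. Among the lower genes they ended those of Lalba (-1.59), Krt14 (-1.16), Retn (-1.10), Cox6b1 (-0.92), Emcn (-0.79), Tie1 (-0.73) and Tpsb2 (-0.37). The mast cell, Hedgehog and oxidative phosphorylation lists did not pass there (adjusted p = 0.277, 0.141 and 0.0613). Slides from 196 on alone, 4 arrays per group, ended the calls of Lad1 (1.12), Fabp3 (-1.14) and the heat shock list (adjusted p = 0.0749). Past the threshold in both, the mean of a gene's probes changed Sema3c to -1.49 and Sufu to 0.42, and quantile normalization changed Acacb to -0.81, Cox6b1 to -0.80 and Fbl to 0.51. Without passing in either, Krt18 (-0.77), Gata3 (-0.32) and Cdh1 (-0.09) turned negative under a common median absolute deviation.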

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

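The tests of stromal lists and cell division genes below, and the test of stroma in the nuclear RNA pattern, were chosen after the values were seen, and the tests of unseen nuclear RNA genes and of gene length before. All were two-sided, and Benjamini-Hochberg adjustment over the 15 exact tests raised the 12 p-values below 0.05 to at most 0.0391.

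Of 410 groups of 6 values checked, 18 had an array far from the other 5, where chance flags about 1 in 20, or 20.5. Terminal end bud replicate 5 stood apart for Sprr1a (4.47), Rrm2 (1.39), Dhh (1.91), Boc (0.54) and Lyve1 (-2.60). Terminal end bud replicate 3 stood apart for Mybbp1a (0.70) and Ccnb2 (-1.32), replicate 4 for Cdh1 (2.73) and Dusp1 (-0.99), and replicate 6 for Cox7a1 (-0.25). Duct replicate 5 stood apart for Actg2 (1.80), Mcm6 (2.05) and the mean of the replication list (0.60). Duct replicate 2 stood apart for Rps10 (2.04), Slc4a4 (-2.72) and Mmp14 (1.57), and duct replicate 4 for Fn1 (0.85) and the mean of the keratinocyte and hair list (-0.0701).

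The ratio to stroma was opposite in the structures, past the threshold in both, for 174 probes, 27 of them higher in terminal end buds and 147 higher in ducts. Named genes among them differed between terminal end buds and ducts by -3.60 for Apod, -1.61 for Mmp3, 0.94 for Gmnn and -0.74 for Ncl in limma's test of the difference. No probe was opposite at 2-fold or more in both. Of 100 splits of the 12 arrays into 6 and 6 drawn from 462, 1 gave as many probes past the threshold as the real one, which was the real split itself with 3295, and the highest other gave 33, so a chance arrangement of the arrays is argued against.

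Stromal lists were lower in terminal end buds than in ducts, and distal stroma carried into the duct samples is a possible explanation. In that case the mean ratio of the brown adipocyte list limits the stroma share of a duct array, on average to 37.5%. Single genes with lower ratios would set a lower limit, which was not tried. Endothelial genes lay 0.21 ± 0.11 (SD, n = 6) above what the share from the list mean allows (exact sign-flip p = 0.0312, the smallest possible, and 0.30 with the same p if the values are natural logarithms), which argues against 1 mixture for them. For adipocyte genes the excess was 0.10 ± 0.14 (SD, n = 6, exact sign-flip p = 0.188, and 0.0625 with natural logarithms), so mixture and tissue difference cannot be told apart at the limit from the list mean, because the excess lies within its spread. Ducts exceeded a mixture of any share by 0.36 ± 0.20 for mast cell genes and 0.34 ± 0.29 for fibroblast genes (SD, n = 6, exact sign-flip p = 0.0312 for both, the smallest possible). The fibroblast excess fell to -0.107 with 1 terminal end bud array as baseline, so it does not argue against a mixture. For mast cells the highest mixture was 0, so their excess argues against it only if a ratio of 0 marks the stroma level. Without a dye swap a dye bias of single probes could shift that level, in the endothelial test as well. The narrower ratios of duct arrays do not account for all of the adipocyte and endothelial differences, which shrank from -0.81 and -0.63 but stayed after quantile normalization, at -0.37 (SE 0.10, exact permutation p = 0.00649) and -0.40 (SE 0.09, exact permutation p = 0.00433). The brown adipocyte list went from -0.87 (SE 0.23) to -0.0829 (SE 0.23, exact permutation p = 0.723) and oxidative phosphorylation from -0.35 (SE 0.11) to 0.0641 (SE 0.12, exact permutation p = 0.584), where array spread and tissue cannot be told apart, since the method makes the lowest ratios of all arrays alike; a different stroma around ducts stays open and untested.

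Mitosis and replication genes were higher in terminal end buds than in ducts, for which a larger epithelial share is a possible explanation. If the epithelium of both structures expressed luminal genes alike, which was not tested, a larger share would move them at least as much. Yet the mitosis list less the luminal list differed by 0.60 (SE 0.15, exact permutation p = 0.00649) and the replication list by 0.42 (SE 0.11, exact permutation p = 0.00866). A lower luminal expression in terminal end buds could hide a larger share, so these values argue against it only under that assumption. After quantile normalization the differences went from 0.81 and 0.63 to 0.66 (SE 0.14, exact permutation p = 0.00433) and 0.50 (SE 0.10, exact permutation p = 0.00649), against the spread of the arrays as the whole cause. More dividing cells in terminal end buds remains as a hypothesis, found and tested on the same data.

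Several RNA-processing factors and the nuclear RNA Neat1 were lower in terminal end buds than in ducts, a pattern noticed in Neat1 (-1.97), Luc7l3 (-0.995), Bclaf1 (-1.05) and 1 of 4 probes of Meg3 (-1.38), whose others lay at -0.33, -0.00333 and 0.03. A list of 36 nuclear RNAs and RNA-processing factors was then written, and its 19 measured members not yet looked at were all lower. Their mean was -0.41 (SE 0.09, exact permutation p = 0.00216, the smallest possible), so the pattern was not limited to the genes first noticed. The permutation ran over arrays, and random sets of genes were not drawn. Limma's threshold was passed by 10 of the 19, against 1455 of all 12913 genes in the same direction. Members ranged from -0.87 for Clk4 to -0.0098 for Son, and the nuclear RNA Malat1 at -0.23 (SE 0.24, limma adjusted p = 0.585) did not pass. Less the median of the 200 genes nearest in genomic length the difference was -0.40 (SE 0.09, exact permutation p = 0.00216), against a length bias. Stroma in the duct samples could only move ratios toward 0, but the mean of the 19 members in ducts was 0.16 ± 0.08 (SD, n = 6, exact sign-flip p = 0.0312), above 0 on all 6 arrays. This too takes a ratio of 0 as the stroma level, which a dye bias of single probes could shift. A difference between the structures in nuclear RNA content and one in how RNA was extracted or amplified may both give the lower values in terminal end buds, and neither was tested.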

How the results depend on the processing

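The subsets by slide number, the fits without the least correlated arrays and the scaled gene lists were chosen after seeing the data. A minimum of 2-fold left 175 higher and 244 lower probes for terminal end bud against duct, 657 and 612 for terminal end bud against stroma, 318 and 106 for duct against stroma, and 231 and 101 in both structures. Slides up to 193 alone, 2 arrays per group, gave 383 and 648, 2354 and 2290, and 1085 and 1088 in the same order. That subset has fewer arrays and only early slides, and which of these mattered was not tested. Under the other settings the counts of the 3 comparisons stayed within 1.5 times their values, and the counts in both structures were not run under them. The probes behind a count could change: quantile normalization kept 888 of the 1463 higher and 1134 of the 1832 lower calls of terminal end bud against duct, among 979 and 1259. Leaving out each array in turn gave 1236 to 1479 higher and 1543 to 1877 lower probes for terminal end bud against duct. Of the named genes under all settings, 6348 results kept their side of the threshold, and 97 lost and 8 gained it. Leaving out an array of the other group leaves the ratios to stroma unchanged, so these counts overstate stability. Some calls that are not printed above were lost too. Without duct replicate 3, Elovl3 (-0.87, adjusted p = 0.0667) and Pdia4 (0.48, adjusted p = 0.0696) lost theirs in terminal end bud against duct. Without duct replicate 2, Cdk1 (0.61, adjusted p = 0.0613), Mcm5 (0.52, 0.0888) and Lyve1 (-0.65, 0.0584) lost theirs in duct against stroma. Turns of sign that passed in neither fit, as for Krt18, Gata3 and Cdh1 above, count among the 6348. Among results that passed in either fit, 1 turned: Cox8b in terminal end bud against duct, at -0.90, was 0.15 after quantile normalization (adjusted p = 0.796), and the cause was not tested. Of gene list results 874 kept their side of the threshold, 60 lost and 45 gained it, and 1 turned, oxidative phosphorylation after quantile normalization (adjusted p = 0.33). Turns that passed in neither test count among the 874, and direction was not compared for fry and the estimated correlation. The labels hold no replicate numbers. Neighbouring slides as a replicate block gave 1378 higher and 1846 lower probes for terminal end bud against duct. Deviations of neighbours correlated by -0.06 to 0.28, with a median of 0.05 against -0.03 for other pairs. The correlation was over 0.1 in 1 of 6 pairs, and 4 of 12 arrays correlated best with their neighbour. So few pairs neither show nor exclude a pairing of the arrays by slide. The filter at 2 arrays removed no probe. Signal over background was not analysed here.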

Other observations

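The tests named here used lists fixed before the data were examined, while the scaled lists, the slide subsets and the single genes of the last paragraph were chosen after values were seen.

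The remaining lists did not pass camera in terminal end buds against ducts. Of 19 macrophage and myeloid genes 1 rose and 1 fell (camera adjusted p = 0.493), of 18 lymphocyte genes 3 rose and 0 fell (0.167), of 16 skeletal muscle genes 1 rose and 2 fell (0.957), of 11 genes of Schwann cells and nerve 1 rose and 1 fell (0.471), and of 11 keratinocyte and hair genes 1 rose and 1 fell (0.161). Only 3 erythrocyte genes were measured, of which 0 passed, and that list was not tested. Of the signalling and structural lists, in mammary transcription factors 7 rose and 4 fell (0.189), in the Wnt pathway 7 and 3 (0.161), in Notch 1 and 5 (0.957), in TGF-beta and BMP 2 and 6 (0.493), and in FGF, EGF, IGF and HGF signalling 7 and 8 (0.957). In axon guidance 6 rose and 5 fell (0.957), in the basement membrane 2 and 3 (0.905), in matrix proteases and inhibitors 5 and 10 (0.123), in apoptosis 4 and 3 (0.957), in cytosolic ribosomal proteins 3 and 3 (0.957), in cholesterol synthesis 3 and 3 (0.957) and in the interferon response 2 and 2 (0.493). Fry, which asks only whether genes of a list move on balance one way, passed for the keratinocyte (adjusted p = 0.000247), lymphocyte (0.00312), matrix protease (0.00445), TGF-beta and BMP (0.0064) and Wnt (0.0124) lists. Camera passed after quantile normalization for matrix proteases (0.024) and ribosomal proteins (0.013), on slides from 196 on for matrix proteases (0.0461), and on slides up to 193 for lymphocytes (0.0478). The median, the mean and the direction of the test differed in sign for the skeletal muscle, Notch, TGF-beta and BMP, axon guidance, basement membrane, apoptosis and ribosomal protein lists.

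Members of the basal and myoepithelial list parted ways. Krt15 (-1.52), Cnn1 (-1.78), Tagln (-1.27) and Mylk (-1.02) were lower in terminal end buds than in ducts beside Krt14 and Myh11, while Actg2 (1.94), Krt6a (0.66) and Cdh3 (0.36) were higher, all past limma's threshold. The transcription factor genes Etv4 (1.43) and Etv5 (1.74) were higher in terminal end buds, as were Dusp6 (0.62) and Spry2 (0.51), while Spry1 (0.49, adjusted p = 0.0865) did not pass and the fixed list of FGF, EGF, IGF and HGF signalling went both ways. Kitl, the ligand of the receptor Kit that mast cells need, was at -0.47 ± 0.38 (SD, n = 6) in terminal end buds and 1.27 ± 0.24 (SD, n = 6) in ducts. Rspo4, a secreted enhancer of Wnt signalling, went the other way, at 0.69 ± 0.35 (SD, n = 6) and -1.05 ± 0.36 (SD, n = 6).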
